A study of Mus musculus with 15 samples.

How the data were processed

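mRNA was measured in 15 libraries of a mouse line named HoxB in the labels, 3 in each of 5 groups: EMPTY, RUNX1-ETO_ONLY, CSF3R_ONLY, RUNX1-ETO_FIRST and CSF3R_FIRST. Per the labels, total RNA was purified on columns with DNase digestion and strand-specific mRNA libraries were sequenced on a BGI DNBSEQ instrument. The authors deposited 1 table of raw counts per gene symbol with 1 column per library, and all columns were used. The submitters' processing notes name Trimmomatic, STAR, DESeq2 and the build mm10 without versions or roles. The counting program, gene annotation, strand setting and handling of reads shared between genes are not given in the sources used here. Counts of genes with close paralogs (mast cell proteases and tryptases, the Ifitm, Prg and haemoglobin families) or overlapping neighbours on the other strand are therefore less certain.

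The table had 52328 entries. The 1 entry naming no gene, which held 0.0179% to 0.0305% of the counts of a library, was left out. Total counts per library were 17007437 to 18178292, and 9 mitochondrial transcripts took 1.15% to 2.89% of them. Genes were kept by the default expression filter of edgeR 4.0.16 within groups, which left 13123 genes. Scaling factors were TMM, from 0.921 to 1.09. CPM values, the read counts scaled to a common library size by edgeR's cpm function, use these factors, and log2 CPM uses a prior count of 2. Values are given as mean ± SD over 3 libraries. A gene with no counts in a group is compared with a floor of 3 counts per library, as "at least N-fold". With 1 to 3 counts in a group, the ratio of counts per total is given with its exact 95% counting interval. Both cover counting error only.

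All libraries were fitted together by robust quasi-likelihood F tests in edgeR under R 4.3.3, with 5 group means and 10 residual degrees of freedom. The 7 pair comparisons and 2 tests of additivity (a double group minus both single groups plus EMPTY, on the log2 scale) were each adjusted by Benjamini and Hochberg over all genes, with a threshold of 0.05. Standard errors (SE) are on the log2 scale, and tests are two-sided. Counts were simulated from the mean of each gene over all libraries and its dispersion, and 12779 simulated genes were tested. Changes were placed in RUNX1-ETO_FIRST alone, in genes above a minimum level. Noise was drawn for each gene on its own, without deviations shared by whole libraries, so the rates may be too favourable. The order comparison recovered 47% of genes changed 1.5-fold and 88% of those changed 2-fold, and 6 of 141 calls were false. The additivity test with the fusion first recovered 18% and 68%, and 4 of 90 calls were false.

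Gene lists were fixed before the data were examined, 25 lists with 397 genes. Those with at least 5 tested members, other than identity checks, were tested by camera in limma 3.58.1 on log2 CPM with a preset correlation of 0.01, adjusted over the 21 lists of a comparison, and again with an estimated correlation. The lists were primary granule, later granule and mature neutrophil, monocyte and macrophage, dendritic cell and antigen presentation, stem and progenitor, granulocyte and monocyte transcription factors, mast cell with basophil and eosinophil, erythroid and megakaryocyte, lymphoid, STAT3 and STAT5 response, MAPK response, interferon response, NF-kB and inflammatory, cell cycle, ribosome biogenesis and MYC target, p53 response, glycolysis, cholesterol synthesis, endoplasmic reticulum and amino acid stress, genes described as raised or as lowered by RUNX1-ETO, and stromal genes. Mitochondrial transcripts, sex-linked genes and the 3 genes of the alleles were described only. Some lists share members, so their results are not independent. Genes described as lowered by RUNX1-ETO share Ctsg, Elane and Mpo with the primary granule list and Cebpa and Spi1 with the transcription factors. Gata1 is in both the mast cell and the erythroid list. A list's members were counted as risen or fallen by the gene test over all genes, and also adjusted over the list alone, which is stated where the number differs or stands as a second pair in brackets. Genes changed at least 2-fold by each single allele formed 4 further sets, tested by camera in the order comparison, which shares no library with their definition.

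Named genes were chosen by a rule fixed before the data were examined. Csf3r, Runx1 and Runx1t1 came first. Then came the largest rises and falls past the threshold with a mean log2 CPM of at least 3 and no overlap between the groups' libraries, so that all 3 libraries of one group lay beyond all 3 of the other, leaving out unnamed gene models. There were 10 of each for the order and single-allele comparisons and 5 for the others, without the overlap condition for additivity. From each list up to 4 members with the largest change past the threshold and up to 2 abundant members not past it were eligible. Gene positions are from GENCODE release M21 on mm10, in which 12799 of the tested genes were matched by symbol. That annotation may not be the one the authors used.

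Alternatives planned beforehand were DESeq2 size factors, library sizes alone, no filter, a filter of CPM over 1 in 3 libraries, a replicate term, only the groups compared in the fit, DESeq2 1.42.0, limma-voom with sample weights, a 2-fold minimum, an estimated correlation, sets without the 2-fold minimum, and each library left out in turn. Alternatives chosen after seeing the data were a fit without 4 libraries low in long transcripts, a correction of each library for a trend with transcript length, and that correction with a replicate term. Replicate numbers carried no batch in the labels. Deviations from group means were correlated between equal numbers in RUNX1-ETO_ONLY against EMPTY (lowest r across genes 0.615) and CSF3R_FIRST against EMPTY (0.392). They were not in the other 5 pair comparisons (lowest r from −0.622 to −0.169). In EMPTY, RUNX1-ETO_ONLY and CSF3R_FIRST the library low in long transcripts was replicate 3, so these correlations do not show that the samples were paired. The replicate term is therefore an alternative only.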

Results

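Strand-specific mRNA libraries were sequenced from a mouse cell line that the labels call HoxB, with the cell type given as Blood. The 15 libraries formed 5 groups of 3 replicates. Cells labelled EMPTY were the controls. RUNX1-ETO_ONLY cells carried the fusion of RUNX1 with ETO (the product of RUNX1T1), a leukaemia fusion transcription factor. CSF3R_ONLY cells carried the receptor for granulocyte colony-stimulating factor with the change T618I. RUNX1-ETO_FIRST and CSF3R_FIRST cells carried both alleles, named by the allele introduced first. The deposited table held raw counts, and total counts per library were 17007437 to 17391045 in EMPTY, 17834284 to 18178292 in RUNX1-ETO_ONLY and 17482995 to 17653679 in CSF3R_ONLY. They were 17942960 to 18138097 in RUNX1-ETO_FIRST and 17919315 to 18068091 in CSF3R_FIRST. Between 16262 and 17242 genes had at least 1 count in a library, and 13123 genes were tested. The labels do not say whether replicates were separate cultures, so each p-value of a gene rests on the spread between these samples, which may be technical alone. The list test sets the members of a list against the other genes. Its p-values therefore do not measure the spread between samples.

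Transcripts of the genes named by the alleles were looked at first. Runx1t1 (chromosome 4, 13743436 to 13893649, plus strand, mm10) had no counts in EMPTY or CSF3R_ONLY. Its mean was 448 ± 61.3 CPM (scaled read counts, SD, n = 3) in RUNX1-ETO_ONLY, 494 ± 99.2 in RUNX1-ETO_FIRST and 711 ± 134 in CSF3R_FIRST. Runx1 (chromosome 16, 92601466 to 92826149, minus strand), a transcription factor of blood development, averaged 90.2 ± 7.79 CPM in EMPTY and 547 ± 29.5 in RUNX1-ETO_ONLY, a 6.06-fold rise. Csf3r (chromosome 4, 126024550 to 126044440, plus strand) averaged 419.6 ± 46.1 CPM in EMPTY, 524 ± 15.3 in RUNX1-ETO_ONLY and 622 ± 4.60 in CSF3R_ONLY. It was 419 ± 20.1 CPM in RUNX1-ETO_FIRST and 397 ± 32.1 in CSF3R_FIRST, and neither double group was shown to differ from EMPTY (adjusted p = 0.994 and 0.454). The sources used here do not give the species of the introduced coding sequences. These counts may therefore miss introduced transcripts that do not align to the mouse genes, or include those that do. The rise of Runx1 in cells with the fusion may thus come from fusion transcripts, from the cells' own gene or from both, which were not separated.

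**Figure D1:**
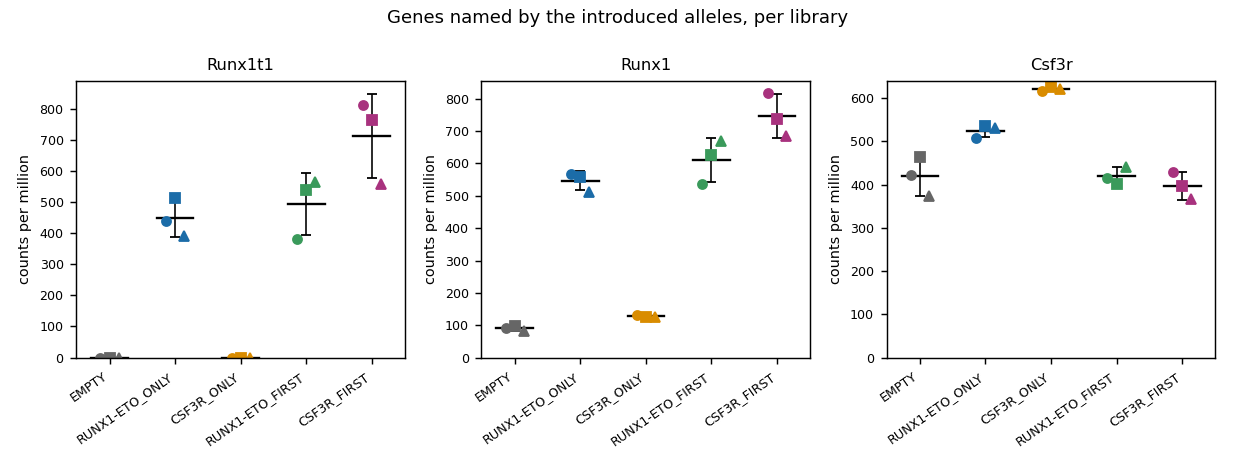
Expression of Csf3r, Runx1 and Runx1t1 in CPM per library in the 5 groups, with the mean as a line and the SD as bars. Runx1t1 was at 0 CPM in every EMPTY and CSF3R_ONLY library and averaged 448, 494 and 711 CPM in the groups with the fusion.

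The first principal component held 50.3% of the variance across libraries and the second 26.7%. Each of EMPTY replicate 3, RUNX1-ETO_ONLY replicate 3, RUNX1-ETO_FIRST replicate 1 and CSF3R_FIRST replicate 3 was low in long transcripts relative to its group, with a correlation across genes between deviation and transcript length of −0.386, −0.376, −0.353 and −0.302. Genes are not independent replicates in these correlations. These libraries fell 1 to a group in 4 of the 5 groups.

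**Figure D2:**
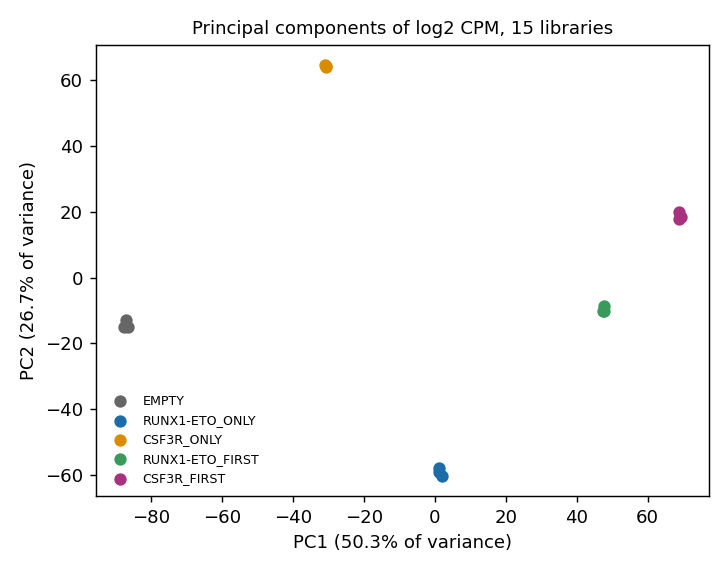
The 15 libraries on the first and second principal components of log2 CPM, which hold 50.3% and 26.7% of the variance. Points are libraries, marked by group, and the first component runs from −87.8 for EMPTY to 69.3 for CSF3R_FIRST.

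The central question of the series is whether the order of the alleles matters, and it was addressed by comparing RUNX1-ETO_FIRST with CSF3R_FIRST. Cells given the fusion first had 70.5-fold more Bnip5 (log2 6.14, SE 0.266, adjusted p = 1.58e-09), at 48.3 ± 4.37 against 0.676 ± 0.380 CPM (SD, n = 3). Bnip5 in EMPTY was near the level of the fusion-first cells, and in CSF3R_ONLY near that of the receptor-first cells. Plxdc2, a plexin-domain membrane protein (chromosome 2, 16356304 to 16755839), was 5.52-fold higher (SE 0.136 on the log2 scale). Plxnb2, a semaphorin receptor, was 4.04-fold higher, and Ccnd2, which encodes cyclin D2 of the G1 phase, was 3.94-fold higher. Cells given the receptor first had 7.38-fold more Saa3, an acute-phase serum amyloid (chromosome 7, 46711998 to 46715700; log2 −2.88, SE 0.153, adjusted p = 1.01e-08), at 30.5 ± 4.16 against 4.13 ± 0.712 CPM. Penk, the enkephalin precursor (chromosome 4, 4133531 to 4138819), was 5.69-fold higher in them, and Arg1, the arginase of the urea cycle and of some macrophages, 5.02-fold higher.

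Further genes higher with the fusion first than with the receptor first were Slc22a3, an organic cation transporter (3.75-fold), and Met, the hepatocyte growth factor receptor (3.66-fold). So were the aldo-keto reductase Akr1c13 (3.31-fold), the secreted Angptl2 (3.16-fold) and the fatty acyl-CoA reductase Far2 (2.93-fold). These folds are between the orders and not against EMPTY. Chdh, choline dehydrogenase, was 2.98-fold higher (log2 1.58, adjusted p = 0.0203). That call ended without RUNX1-ETO_FIRST replicate 2 or 3 or CSF3R_FIRST replicate 1 or 3 (adjusted p = 0.0825, 0.0608, 0.0723 and 0.106), and without CSF3R_FIRST replicate 2 the log2 value was 2.21. Genes higher with the receptor first included the neuronal pentraxin Nptx1 (5.48-fold) and the sphingosine kinase Sphk1 (4.90-fold). Others were the eosinophil granule protein Prg3 (4.73-fold) and the collagen chain Col5a3 (4.57-fold). The netrin receptor family member Neo1 (4.57-fold), the glypican Gpc4 (4.30-fold) and the acid phosphatase Acpp (4.09-fold) were also higher there. Runx1t1 differed by −0.53 (SE 0.172, adjusted p = 0.0568), not past the threshold here but past it under 8 of the alternatives tried, at adjusted p from 4.5e-07 to 0.0494. Runx1 fell by 0.29 on the log2 scale (adjusted p = 0.044), a call that ended with library sizes alone (0.206), with only the groups compared (0.0678) and without RUNX1-ETO_FIRST replicate 1 or 2 or CSF3R_FIRST replicate 1 or 2 (0.167, 0.0846, 0.171 and 0.0892). Csf3r was not past the test (log2 0.08, adjusted p = 0.585).

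**Figure D3:**
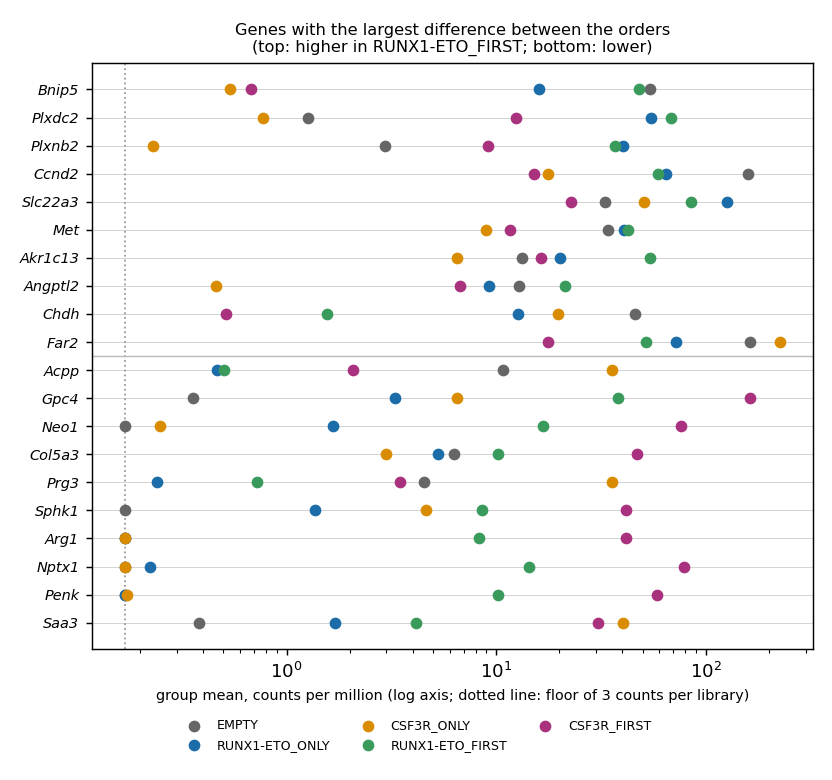
Mean CPM on a log axis in each of the 5 groups for the 20 genes with the largest differences between RUNX1-ETO_FIRST and CSF3R_FIRST. The dotted line is the floor of 3 counts per library, and Bnip5 ranges from 0.540 CPM in CSF3R_ONLY to 54.3 in EMPTY.

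Mast cell, basophil and eosinophil genes were lower with the fusion first. Of 20 tested members, 17 fell and 0 rose (18 and 1 adjusted over the list alone; camera adjusted p = 1.6e-14). The mast cell chymase Cma1 averaged 945 ± 104 against 3378 ± 336 CPM (log2 −1.84), and Fcer1a, the chain of the IgE receptor that binds IgE (chromosome 1, 173221284 to 173227214), 32.8 against 102 CPM (log2 −1.64). Some members (Mcpt4, the tryptases, Prg2 and Prg3) have close paralogs, and how shared reads were counted is not given in the sources used here. Later granule and mature neutrophil genes were lower too, with 21 of 28 fallen and 0 risen (24 and 0 over the list alone; adjusted p = 1.6e-14). The collagenase Mmp8 fell (log2 −1.70), as did the calprotectin subunits S100a9 (log2 −1.55) and S100a8 (log2 −1.47). Of 11 primary granule genes 1 rose and 4 fell (1 and 7 over the list alone; adjusted p = 0.0126, but adjusted p = 0.432 with an estimated correlation). The lysozyme gene Lyz2 fell by 1.24, whereas Mpo, myeloperoxidase, was not past the test (log2 0.15, adjusted p = 0.273). Monocyte and macrophage genes went the same way, with 10 of 19 fallen and 1 risen (11 and 1; adjusted p = 6.35e-05), among them Csf1r, the receptor for macrophage colony-stimulating factor (log2 −1.64). Of 17 erythroid and megakaryocyte genes 5 fell and 1 rose (6 and 1; adjusted p = 0.0376, but adjusted p = 0.324 with an estimated correlation), with the transcription factor Gata1 at −1.06. Granulocyte and monocyte transcription factors had 5 of 14 fallen and 1 risen (6 and 2; adjusted p = 0.0389, but adjusted p = 0.324 with an estimated correlation). Klf2 fell (log2 −1.09), Irf8 rose by 1.28 on the log2 scale, and Cebpa was not past the test (adjusted p = 0.0943). The erythroid call ended without RUNX1-ETO_FIRST replicate 3 (0.0694), without CSF3R_FIRST replicate 3 (0.108), without the 4 libraries low in long transcripts (0.0686) and with a length correction (0.0515). The transcription factor call ended without RUNX1-ETO_FIRST replicate 2 (0.0792) or 3 (0.0523) or CSF3R_FIRST replicate 1 (0.0523).

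Signalling lists also differed between the orders. Among 18 NF-kB and inflammatory genes 11 fell with the fusion first and 0 rose (12 and 1 over the list alone; adjusted p = 4.78e-06). Il1b, the cytokine interleukin 1 beta, fell (log2 −1.29), as did its antagonist Il1rn (log2 −1.59) and the chemokine Ccl2 (log2 −1.07), while Ccl3 was not past the test (log2 −0.01). STAT3 and STAT5 response genes had 11 of 21 fallen and 2 risen (13 and 2; adjusted p = 0.00307, but adjusted p = 0.0539 with an estimated correlation). The signalling inhibitor Socs3 fell (log2 −0.83), as did Gadd45g (log2 −1.20), whereas Socs2 rose by 1.45 beside Ccnd2. Interferon response genes had 8 of 21 risen and 3 fallen (9 and 5; adjusted p = 0.0276, but adjusted p = 0.0539 with an estimated correlation). Oasl2, an oligoadenylate synthetase-like gene, rose by 2.29, and the GTPase gene Iigp1 was at 1.54 CPM against 0, at least 8.57-fold higher. That list's call ended with library sizes alone (0.0829) and without the 4 libraries low in long transcripts (0.123).

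Cell cycle genes were higher with the fusion first: 16 of 21 rose and 0 fell (18 and 0 over the list alone; adjusted p = 5.15e-10). The DNA helicase subunit Mcm7 rose by 0.45 and the mitotic genes Birc5, Aurkb and Plk1 by 0.45, 0.43 and 0.42 on the log2 scale. Ribosome biogenesis and MYC target genes had 5 of 16 risen and 0 fallen (8 and 0; adjusted p = 0.000262), such as the ribosomal RNA regulator Mybbp1a at 0.35. Of 13 glycolysis genes 0 passed singly (0 over the list alone; adjusted p = 0.0348 with the list lower, but adjusted p = 0.364 with an estimated correlation), and Gapdh was at −0.23. The glycolysis call ended with library sizes alone (0.0829) and without RUNX1-ETO_FIRST replicate 2 (0.0792) or 3 (0.0508).

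The mast cell, neutrophil, monocyte, NF-kB, cell cycle and ribosome lists also passed with an estimated correlation (adjusted p from 0.00119 to 0.013). The remaining lists were not past the list test in this comparison. Of 22 stem and progenitor genes 4 rose and 6 fell (6 and 7 over the list alone; adjusted p = 0.769), with Ly6a, the surface antigen Sca-1, at 328 against 943 CPM. Dendritic cell genes had 1 of 7 risen and 3 fallen (1 and 5; 0.0653), lymphoid genes 2 and 1 of 7 (2 and 2; 0.769) and MAPK response genes 1 and 3 of 18 (1 and 5; 0.509). Il7r, the interleukin 7 receptor chain, fell (log2 −1.29), as did Ccnd1, cyclin D1 (log2 −2.12). Genes of the p53 response had 0 risen and 2 fallen of 13 (0 and 2; 0.212), cholesterol synthesis genes 0 and 1 of 15 (0 and 1; 0.0566) and endoplasmic reticulum stress genes 1 and 2 of 10 (1 and 2; 0.12). Fas, the death receptor, fell (log2 −1.20), as did the chaperone Hspa5 (log2 −0.45). Genes described as raised by RUNX1-ETO had 0 risen and 2 fallen of 7 (1 and 2; 0.509), and those described as lowered by it 0 and 2 of 9 (0 and 3; 0.46). Lists outside the list test were small or identity checks. Of 4 stromal genes 1 fell (2 over the list alone), of 8 mitochondrial transcripts 0 passed, Xist did not pass, and of the 3 allele genes 1 fell (2 over the list alone).

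**Figure D4:**
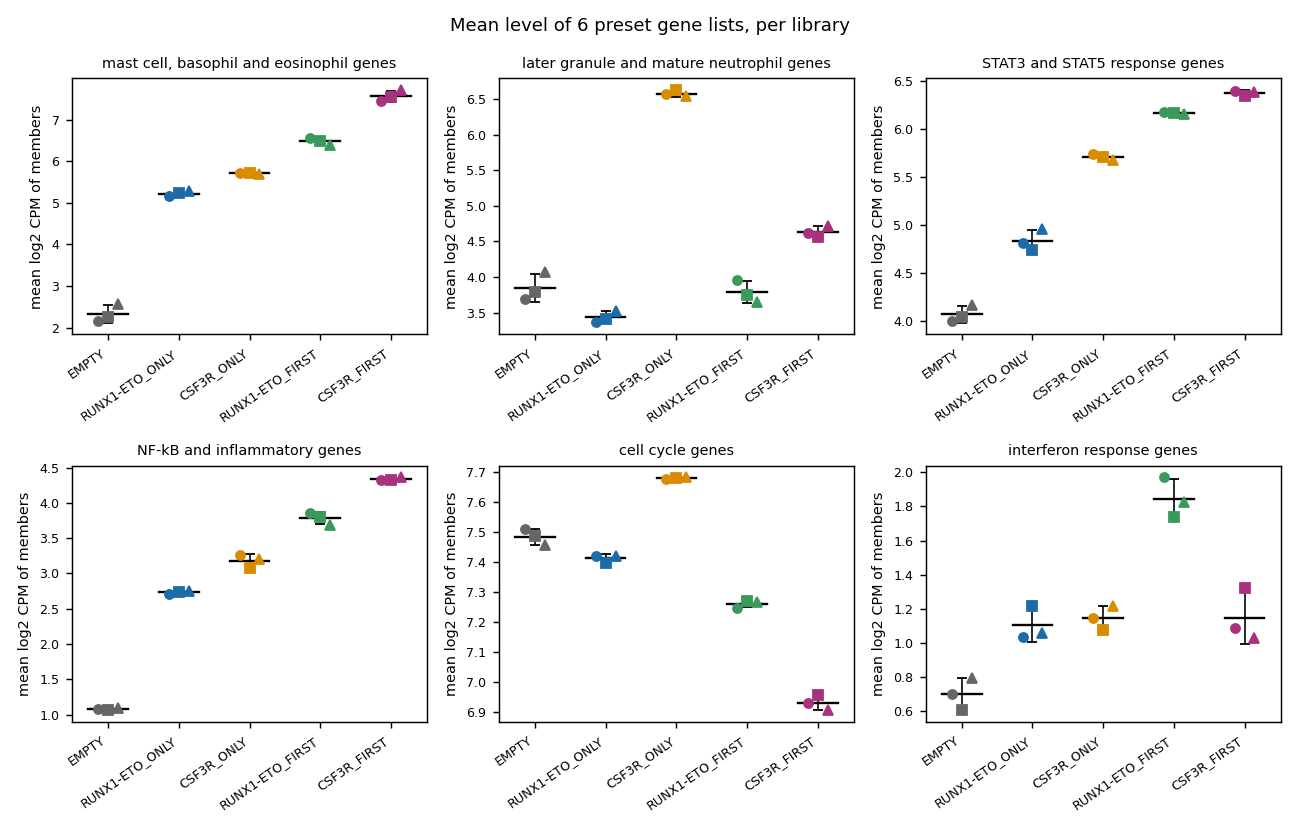
Mean log2 CPM of the tested members of 6 preset lists (mast cell, later neutrophil, STAT, NF-kB, cell cycle, interferon) in each of the 15 libraries. Mast cell members were lower in RUNX1-ETO_FIRST than in CSF3R_FIRST (17 of 20 fell), and cell cycle members were higher (16 of 21 rose).

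In all, 2407 of 13123 genes differed between the orders, 948 higher and 1459 lower with the fusion first, of which 633 also differed at least 2-fold. Without RUNX1-ETO_FIRST replicate 3 the split was 510 higher and 1208 lower, and without CSF3R_FIRST replicate 3 it was 526 and 1304. Without the 4 libraries low in long transcripts 4449 genes differed, and with limma-voom and sample weights 4305. With library sizes alone the median of all genes was 0.10 rather than 0.00 on the log2 scale and the split was 1842 higher and 1131 lower, so the balance of directions depended on the scaling.

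To place the fusion on its own, RUNX1-ETO_ONLY was compared with EMPTY. Tjp1, a tight junction scaffold, rose from no counts to 126 ± 22.7 CPM (SD, n = 3), at least 740.4-fold against a floor of 3 counts per library. Also from no counts, Etl4 rose at least 405-fold, the metalloproteinase Adamts9 129.8-fold and the actin nucleator Cobl 66.4-fold. The mast cell protease genes Mcpt4 (chromosome 14, 56059629 to 56062313) and Tpsb2 rose to 48.5 and 435 CPM. Tpsb2 was 345-fold higher (log2 8.43, SE 0.197, adjusted p = 7.53e-14), and the count ratio of Mcpt4 was 1281 (95% counting interval 354 to 10581). Thbs1, the matrix protein thrombospondin 1, fell 26.7-fold from 1735 ± 476 to 65.0 ± 3.49 CPM, and Bace1, the beta-secretase (chromosome 9, 45838580 to 45864399), fell 40.5-fold (log2 −5.34, SE 0.240, adjusted p = 6.76e-11).

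The count ratio of Ccl2 was 887 (159 to 35052), and Cd55, the complement decay-accelerating factor, rose 538-fold (log2 9.07, or 10.28 without EMPTY replicate 1). The few EMPTY counts of Mcpt4 and Ccl2 lay in EMPTY replicate 3, without which fitted log2 values moved from 10.08 and 9.34 to 12.76 and 11.23. Carry-over of reads from other libraries into EMPTY replicate 3 was not tested, and where present it would make such ratios too small. Such intervals and floors cover counting error only. Other large falls were those of the interferon-induced Ifitm1 (24.8-fold), Acpp (22.9-fold), the centriole appendage gene Cep164 (18.6-fold), the adhesion molecule Ncam1 (18.0-fold), osteopontin Spp1 (16.8-fold), the GTPase Rhou (16.3-fold) and the neutrophil lectin Fcnb (15.8-fold). Prg3 fell 18.3-fold (log2 −4.20, or −4.82 without RUNX1-ETO_ONLY replicate 3). Runx1t1 was at least 2627-fold higher, and Csf3r rose by 0.32 (adjusted p = 0.00647, or 0.0838 with only the groups compared).

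Among the preset lists, 16 of 20 mast cell genes rose with the fusion alone and 3 fell (16 and 3 adjusted over the list alone; camera adjusted p = 3.08e-10), and Cma1 rose by 7.32. NF-kB and inflammatory genes had 14 of 18 risen and 3 fallen (adjusted p = 0.000445), with the cytokine Il6 up by 5.95 and the chemokine Ccl4 by 5.36. These were the lists that also passed with an estimated correlation (adjusted p = 0.0476 and 0.0268). Erythroid and megakaryocyte genes had 9 of 17 risen and 2 fallen (adjusted p = 0.00166, but adjusted p = 0.14 with an estimated correlation), with Gata1 up by 3.62. STAT response genes had 14 of 21 risen and 4 fallen (adjusted p = 0.000946, but adjusted p = 0.0742 with an estimated correlation), such as Socs1 and Cish, both feedback inhibitors, at 2.78 and 2.78. Stem and progenitor genes had 13 of 22 risen and 6 fallen (adjusted p = 0.0116, but adjusted p = 0.0944 with an estimated correlation), and Ly6a went from 0.400 to 24.6 CPM. Genes described as raised by RUNX1-ETO had 3 of 7 risen and 0 fallen (adjusted p = 0.0214, but adjusted p = 0.103 with an estimated correlation), including Cd34, the progenitor surface marker (log2 2.29).

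Lists that were lower with the fusion alone began with the primary granule genes, of which 7 of 11 fell and 2 rose (7 and 3 over the list alone; adjusted p = 0.00762, but adjusted p = 0.373 with an estimated correlation). Elane, neutrophil elastase, went from 1917 ± 701 to 199.6 ± 30.7 CPM, and Mpo from 45048 to 18223 CPM. Those described as lowered by RUNX1-ETO had 6 of 9 fallen and 1 risen (adjusted p = 0.00509, but adjusted p = 0.14 with an estimated correlation), with Spi1 at −1.23 and Cebpa at −0.98, both myeloid transcription factors. Glycolysis genes had 10 of 13 fallen (adjusted p = 0.000589, but adjusted p = 0.14 with an estimated correlation), among them Gpi1 at −0.86 and Pkm at −0.77. Endoplasmic reticulum and amino acid stress genes had 7 of 10 fallen (adjusted p = 0.00116, but adjusted p = 0.199 with an estimated correlation), such as asparagine synthetase Asns at −0.95. Later neutrophil genes had 11 of 28 fallen and 5 risen (13 and 5; adjusted p = 0.0299, but adjusted p = 0.373 with an estimated correlation), and that call ended without EMPTY replicate 3 (0.0913). Altogether 5117 genes differed, 2724 higher and 2393 lower, and 2046 of them by at least 2-fold. The split with library sizes alone was 3268 higher and 1997 lower. With only these groups fitted the count was 3388. Deviations were correlated between equal replicate numbers here, and a replicate term gave 5262.

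For the receptor on its own, CSF3R_ONLY was compared with EMPTY. Mcpt1, a mast cell protease (chromosome 14, 56017971 to 56020384), went from 0.893 ± 1.35 to 893 ± 36.0 CPM (SD, n = 3; log2 10.01, SE 0.480, adjusted p = 1.85e-10). Fcer1a rose from no counts, at least 113-fold, and Lipg, endothelial lipase, rose 444-fold (log2 8.79, SE 0.218). Gzmb, granzyme B, rose 549-fold and Mcpt2 512-fold. Tifab fell 187-fold (chromosome 13, 56173704 to 56178885; log2 −7.55, SE 0.237), Bnip5 99.2-fold and Irf8, a transcription factor of monocyte and dendritic cell development, 10.7-fold.

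The lipoxygenase gene Alox8 had a count ratio of 1073 (367 to 5206), Mcpt4 of 852 (236 to 7045) and Tph1, tryptophan hydroxylase of serotonin synthesis, of 474 (162 to 2303). Sphk1 rose at least 27.1-fold. The EMPTY level of several of these genes rested on EMPTY replicate 3. Without it fitted log2 values were 12.86 for Mcpt1, 12.32 for Gzmb, 10.57 for Mcpt2, 12.16 for Mcpt4, 10.76 for Alox8 and 9.58 for Tph1, and without EMPTY replicate 1 that of Gzmb was 8.50. Carry-over from other libraries was not tested for these genes either, so the folds and count ratios given for them rest on EMPTY levels of uncertain origin. Falls included Angptl2 (27.4-fold), the B-cell transcription factor Pou2f2 (13.2-fold), Plxnb2 (12.5-fold), the phosphatase Ptprf (10.1-fold), the integrin Itga9 (9.46-fold), Ccnd2 (9.07-fold) and Fcnb (7.04-fold). Csf3r rose by 0.57 (SE 0.0844, adjusted p = 7.31e-05) and Runx1 by 0.50 (adjusted p = 0.000749).

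Nearly all later granule and mature neutrophil genes rose with the receptor alone, 27 of 28, and the other, Fcnb, fell (27 and 1 adjusted over the list alone; camera adjusted p = 6.63e-20). Mmp9, a gelatinase, rose 326-fold to 51.6 ± 1.72 CPM, the resistin-like Retnlg 171-fold and Mmp8 52.8-fold. Mast cell genes had 19 of 20 risen (adjusted p = 1.99e-18), with Cma1 up 202-fold. NF-kB and inflammatory genes had 17 of 18 risen (18 over the list alone; adjusted p = 2.8e-13), including Il6 at 19.9-fold. STAT response genes had 19 of 21 risen and 2 fallen (adjusted p = 5.28e-12), with Socs1 up by 3.48. Erythroid genes had 12 of 17 risen (13 over the list alone; adjusted p = 3.39e-07), monocyte genes 11 of 19 risen and 3 fallen (12 and 3; adjusted p = 0.00195) and p53 response genes 7 of 13 risen (adjusted p = 0.0116). The galectin gene Lgals3 rose by 2.55 and Zmat3 of the p53 list by 2.29. Ribosome biogenesis and MYC target genes fell, 13 of 16 (14 over the list alone; adjusted p = 6.44e-06), such as spermidine synthase Srm at −0.64 and ornithine decarboxylase Odc1 at −0.47. Cholesterol synthesis genes had 12 of 15 risen (13; adjusted p = 6.44e-06, but adjusted p = 0.0559 with an estimated correlation), such as Fdps at 0.86. The other lists that passed here held with an estimated correlation, with adjusted p from 0.000202 to 0.0367. Primary granule genes were not past the list test (3 risen, 3 fallen; adjusted p = 0.798), and Mpo fell by 0.81. Of 11 stromal and endothelial genes 4 were expressed enough to be tested, too few for the list test. Against EMPTY 3 of these rose with the receptor alone, 2 rose and 1 fell with the fusion alone, 3 rose with the fusion first and 4 with the receptor first, and whether other cells were present was not tested. In total 4347 genes differed, 2617 higher and 1730 lower, and 1505 by at least 2-fold. With library sizes alone 2247 were higher and 2333 lower.

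RUNX1-ETO_FIRST was next set against EMPTY. Runx1t1 was at least 2898-fold, Tjp1 at least 549.8-fold and Fcer1a at least 193-fold higher than a floor of 3 counts per library. Mcpt4 reached 246 ± 33.7 CPM (SD, n = 3), a count ratio of 6494 (1797 to 53628), and without EMPTY replicate 3 its fitted log2 value moved from 12.42 to 15.09. Bace1 fell 168-fold (log2 −7.39, SE 0.296, adjusted p = 1.06e-11), Fcnb 122-fold, Chdh 29.4-fold, Tifab 29.2-fold and the inhibitory lectin Clec12a 24.9-fold. Mast cell genes had 16 of 20 risen and 3 fallen (camera adjusted p = 1.89e-10), STAT response genes 19 of 21 risen (7.66e-10), NF-kB genes 15 of 18 risen (4.96e-08) and interferon response genes 15 of 21 risen (0.000327). Examples were Tpsb2 at 9.36, Socs1 at 5.45, Il6 at 7.56 and the guanylate-binding Gbp2 at 4.59. Cell cycle genes fell, 14 of 21 with 1 risen (0.00183), including the helicase subunit Mcm6 at −0.68. Genes described as raised by RUNX1-ETO had 6 of 7 risen (0.00547), with Jup, the junction protein plakoglobin, at 2.82. These 6 lists also passed with an estimated correlation (adjusted p from 0.00196 to 0.035).

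Among the 8 lists whose call was lost with an estimated correlation, cholesterol synthesis genes all rose, 15 of 15 (adjusted p = 5.23e-06, but adjusted p = 0.0591 with an estimated correlation), with Hmgcs1, HMG-CoA synthase, at 1.29. Erythroid genes had 10 of 17 risen (0.000532, but adjusted p = 0.0664 with an estimated correlation) and primary granule genes 7 of 11 fallen (0.021, but adjusted p = 0.49 with an estimated correlation), with Elane at −3.19. Stem genes had 12 of 22 risen, p53 genes 7 of 13, MAPK genes 11 of 18, while ribosome genes had 6 of 16 fallen and genes described as lowered by RUNX1-ETO 5 of 9. Their adjusted p values were 0.0293, 0.0293, 0.0475, 0.0229 and 0.00898, and adjusted p = 0.0742, 0.0664, 0.141, 0.0591 and 0.133 with an estimated correlation. The MAPK call ended with DESeq2 size factors (0.0511), a replicate term (0.0542), a length correction (0.0676) and without EMPTY replicate 2 (0.0581). The stem call ended with a length correction (0.0516) and, like the p53 call, without the 4 libraries low in long transcripts (0.0551 and 0.0536). Adjusted over the list alone the counts were 2 risen for cell cycle, 8 fallen for primary granule, 4 fallen for ribosome genes and 7 fallen for genes described as lowered by RUNX1-ETO. Later neutrophil genes were not past the list test (8 risen and 13 fallen, or 10 and 15 over the list alone; adjusted p = 0.412). In total 5768 genes differed, 3114 higher and 2654 lower, and 2341 by at least 2-fold. Scaled by library sizes alone, 2877 were higher and 3085 lower.

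CSF3R_FIRST was likewise compared with EMPTY. Runx1t1 was at least 4173-fold, Fcer1a at least 601-fold and Nptx1 at least 461-fold higher. Mcpt4 reached 698 ± 11.4 CPM (SD, n = 3), a count ratio of 18458 (5109 to 152420), with a fitted log2 value of 13.93, or 16.62 without EMPTY replicate 3. Bace1 fell 139-fold (log2 −7.12, or −7.95 without CSF3R_FIRST replicate 1), Chdh 87.7-fold (log2 −6.46, or −7.09 without CSF3R_FIRST replicate 2), Fcnb 89.0-fold (log2 −6.48, or −5.86 without the 4 libraries low in long transcripts), Bnip5 79.2-fold and Tifab 46.1-fold. Mast cell genes had 16 of 20 risen and 2 fallen (camera adjusted p = 7.15e-11), NF-kB genes 15 of 18 risen (4.41e-09), STAT response genes 18 of 21 risen (1.47e-08) and genes described as raised by RUNX1-ETO 6 of 7 risen (0.00705). Cma1 rose by 10.90, Il6 by 8.05, Socs1 by 6.17 and Cd34 by 1.75. Falls were seen in 19 of 21 cell cycle genes (1.05e-06) and 15 of 16 ribosome biogenesis genes (0.000377), such as Aurkb at −0.94 and the nucleolar protein nucleolin, Ncl, at −0.49. These 6 lists passed with an estimated correlation too (adjusted p from 0.00104 to 0.04).

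Cholesterol synthesis genes had 14 of 15 risen, erythroid genes 13 of 17, p53 genes 8 of 13, glycolysis genes 9 of 13 and MAPK genes 11 of 18, with Hmgcs1 at 1.59, Gata1 at 5.32 and the glucose transporter Slc2a1 at 0.85. Their adjusted p values were 5.05e-06, 0.000295, 0.0186, 0.043 and 0.043, and adjusted p = 0.0568, 0.0627, 0.0556, 0.321 and 0.134 with an estimated correlation. Genes described as lowered by RUNX1-ETO had 6 of 9 fallen (adjusted p = 0.0481, but adjusted p = 0.244 with an estimated correlation). Deviations were correlated between equal replicate numbers in this comparison, and with a replicate term that list was at 0.0509. Its call also ended with library sizes alone (0.0587), without the 4 libraries low in long transcripts (0.0603), and without EMPTY replicate 3 (0.0558) or CSF3R_FIRST replicate 1 (0.0546). The glycolysis call ended without EMPTY replicate 1 (0.0572) or 2 (0.0552) and the MAPK call without CSF3R_FIRST replicate 1 (0.0588). Adjusted over the list alone 16 ribosome genes fell, and 9 p53, 10 glycolysis and 12 MAPK genes rose. Altogether 7021 genes differed, 3516 higher and 3505 lower, and 2803 by at least 2-fold; a replicate term gave 7249. With library sizes alone the median of all genes was −0.19 rather than −0.05 on the log2 scale, and 2942 genes were higher and 4831 lower.

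The effect of the receptor in cells that already had the fusion was read from RUNX1-ETO_FIRST against RUNX1-ETO_ONLY. Mcpt1 rose 1033-fold to 327 ± 52.6 CPM (SD, n = 3; log2 10.01, SE 0.520, adjusted p = 1.25e-09), Tph1 247-fold, Alox8 102-fold and Gzmb 114-fold (log2 6.83, or 7.42 without RUNX1-ETO_ONLY replicate 2). The semaphorin co-receptor Nrp2 had a count ratio of 232 (63.7 to 1919), and its fitted log2 value of 7.59 was 10.14 without RUNX1-ETO_ONLY replicate 1. Chdh fell 8.16-fold, Fcnb 7.71-fold, Tifab 5.64-fold, the nuclear protein Aff3 4.27-fold and Bace1 4.14-fold. Csf3r itself fell by 0.32 on the log2 scale (adjusted p = 0.00961). STAT response genes had 16 of 21 risen and 0 fallen (camera adjusted p = 1.14e-12), such as Osm, the cytokine oncostatin M, at 2.77. Cholesterol synthesis genes had 15 of 15 risen (5.31e-12), mast cell genes 15 of 20 risen (3.15e-09), NF-kB genes 15 of 18 risen (5.98e-09), glycolysis genes 12 of 13 risen (2.63e-08), interferon response genes 9 of 21 risen (0.000688), monocyte genes 10 of 19 risen (0.00208) and p53 genes 7 of 13 risen (0.015). Mvd of the cholesterol list rose by 1.43, Cyp11a1 of the mast list by 3.29, Pkm by 0.88 and Lgals3 by 3.49. Cell cycle genes had 10 of 21 fallen (0.00517) and ribosome genes 5 of 16 (0.0031), with Mcm7 at −0.33 and Nop58 at −0.37. These 10 lists passed with an estimated correlation as well (adjusted p from 0.000933 to 0.0427). Later neutrophil genes had 14 of 28 risen and 6 fallen (0.00517, but adjusted p = 0.311 with an estimated correlation), transcription factors 7 of 14 risen (0.00517, but adjusted p = 0.114 with an estimated correlation) and endoplasmic reticulum stress genes 6 of 10 risen (0.00109, but adjusted p = 0.183 with an estimated correlation). Adjusted over the list alone 10 interferon genes, 7 stress genes and 8 transcription factors rose. In total 3454 genes differed, 2097 higher and 1357 lower, and 1112 by at least 2-fold. With library sizes alone the median of all genes was −0.14 rather than −0.02 on the log2 scale and the split was 1668 and 2700.

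For the fusion in cells that already had the receptor, CSF3R_FIRST was compared with CSF3R_ONLY. Runx1t1 was at least 4093-fold, Nptx1 at least 452-fold and Adamts9 at least 40.4-fold higher. Penk rose 323-fold to 58.4 ± 1.61 CPM (SD, n = 3; log2 8.33, SE 0.274, adjusted p = 1.73e-12), and Arg1 had a count ratio of 718 (245 to 3486), its fitted log2 value of 9.32 being 12.53 without CSF3R_ONLY replicate 3. Bace1 fell 63.3-fold (log2 −5.98, or −6.82 without CSF3R_FIRST replicate 1), Chdh 37.6-fold (log2 −5.23, or −5.87 without CSF3R_FIRST replicate 2), Ifitm6 37.4-fold, the NADPH oxidase subunit Cybb 32.3-fold and the granule protein Ngp 22.8-fold. Csf3r fell by 0.65 on the log2 scale (adjusted p = 1.17e-05). Later neutrophil genes had 24 of 28 fallen and 4 risen (camera adjusted p = 3e-09), with Mmp9 at −4.18, and cell cycle genes 20 of 21 fallen (2.46e-09), with the ribonucleotide reductase subunit Rrm2 at −1.14. Mast cell genes had 15 of 20 risen and 4 fallen (2.58e-07), MAPK genes 14 of 18 risen (0.000291), stem genes 12 of 22 risen and 4 fallen (0.00155), NF-kB genes 11 of 18 risen and 4 fallen (0.00499) and genes described as raised by RUNX1-ETO 4 of 7 risen (0.00611). Tpsb2 rose by 5.94, Phlda1 by 3.88, Ly6a by 4.13 and Ccl4 by 3.81. These 7 lists held with an estimated correlation (adjusted p from 0.00131 to 0.0424). Dendritic cell and antigen presentation genes had 6 of 7 risen (0.000877, but adjusted p = 0.0915 with an estimated correlation), such as the invariant chain Cd74 at 5.57, STAT genes 11 of 21 risen and 5 fallen (0.0199, but adjusted p = 0.122 with an estimated correlation), and cholesterol synthesis genes 8 of 15 risen (0.0208, but adjusted p = 0.377 with an estimated correlation). The STAT call ended without the 4 libraries low in long transcripts (0.0583). Adjusted over the list alone 7 dendritic cell genes, 9 cholesterol synthesis genes and 5 genes described as raised by RUNX1-ETO rose. In total 5895 genes differed, 2924 higher and 2971 lower, and 2240 by at least 2-fold. Rises were the more numerous when any 1 of the 6 libraries was left out, and the balance also depended on the scaling, with 2520 higher and 3642 lower with library sizes alone and 3092 higher and 2734 lower with DESeq2 size factors.

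Whether both alleles together gave the sum of their separate effects was tested on the log2 scale, as the double group minus both single groups plus EMPTY. A sum on this scale is a product of folds. A gene can therefore lie below it and still be higher with both alleles than with either alone. With the fusion first Bnip5 stood 8.23 above the sum (SE 0.331, adjusted p = 3.36e-10): its levels were 54.3 CPM in EMPTY, 16.0 with the fusion, 0.540 with the receptor and 48.3 with both (n = 3 each). Angptl2 stood 5.99, Tifab 5.05 and Spp1 4.59 above the sum. Retnlg, raised by the receptor alone to 33.6 CPM but at 1.80 with both alleles, stood below the sum (log2 −7.18, SE 0.427). Its EMPTY level was only just above the floor of 3 counts per library, so the size of that departure is uncertain. Genes at or under the floor of 3 counts per library in EMPTY are given as levels only, in the order EMPTY, fusion, receptor and both: Tjp1 had 0, 126, 0.502 and 93.7 CPM, Sphk1 0, 1.36, 4.62 and 8.54, Penk 0.0968, 0.104, 0.174 and 10.3, and Mcpt4 0.0400, 48.5, 32.3 and 246.

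Lists below the sum with the fusion first were the later neutrophil genes (21 of 28 below, 1 above; camera adjusted p = 3.64e-17), mast cell genes (15 of 20; 2.69e-15), erythroid genes (7 of 17; 4.31e-08), NF-kB genes (10 of 18; 2.83e-05), cell cycle genes (8 of 21; 0.000102) and STAT genes (13 of 21, with 3 above; 0.0003). All 6 passed with an estimated correlation (adjusted p from 0.0107 to 0.0316). Below the sum did not always mean lower than with a single allele. Mast cell genes averaged 6.4 to 6.6 log2 CPM in RUNX1-ETO_FIRST libraries, against at most 5.3 in RUNX1-ETO_ONLY and 5.7 in CSF3R_ONLY. The NF-kB and STAT lists were likewise higher with both alleles than with either. The later neutrophil, erythroid and cell cycle lists were not. Cma1 was at −5.92, Gfi1b, an erythroid and megakaryocyte transcription factor, at −4.71 and Il6 at −2.70. Above the sum were glycolysis genes (6 of 13), endoplasmic reticulum stress genes (7 of 10), cholesterol synthesis genes (4 of 15), genes described as lowered by RUNX1-ETO (4 of 9), dendritic cell genes (3 of 7) and transcription factors (5 of 14), with Trib3 at 1.68 and Irf8 at 3.06. Their adjusted p values were 1.66e-05, 5.31e-05, 0.000392, 0.0161, 0.0205 and 0.035, and adjusted p = 0.092, 0.129, 0.129, 0.172, 0.2 and 0.2 with an estimated correlation. The transcription factor call ended without EMPTY replicate 2 (0.0631) or 3 (0.131) and without the 4 libraries low in long transcripts (0.227), the lowered-gene call without EMPTY replicate 3 (0.0604) and without the 4 libraries (0.0649), and the dendritic call without EMPTY replicate 3 (0.0525) or RUNX1-ETO_ONLY replicate 2 (0.0597). Adjusted over the list alone, those below were 22 neutrophil, 18 mast cell, 12 NF-kB, 10 cell cycle and 15 STAT genes, and those above 8 glycolysis, 8 stress, 7 cholesterol synthesis and 5 genes described as lowered. In total 2078 genes departed from the sum, 842 above and 1236 below, and 921 by at least 2-fold. The count was 3466 without the 4 libraries and 3480 with limma-voom and sample weights.

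With the receptor first Tifab stood 4.39 above the sum (SE 0.390, adjusted p = 1.09e-06), Angptl2 4.32, Col5a3 4.21 and Spp1 3.55, and Retnlg stood below it (log2 −6.09, SE 0.421). Levels with both alleles (n = 3 each) were 58.4 CPM for Penk, 42.9 for Tjp1, 698 for Mcpt4 and 66.2 for Ccl2, which had 0.0200 CPM in EMPTY, 16.8 with the fusion and 4.69 with the receptor. Cell cycle genes were below the sum, 18 of 21 (camera adjusted p = 5.81e-10), as was the cyclin Ccne2 at −1.18, and this list alone passed with an estimated correlation (adjusted p = 0.000993). Also below were later neutrophil genes (19 of 28, with 4 above), erythroid genes (8 of 17) and mast cell genes (10 of 20, with 1 above), at adjusted p = 1.44e-06, 8.9e-05 and 0.00116, and adjusted p = 0.109, 0.109 and 0.161 with an estimated correlation. Mast cell genes nevertheless averaged 7.4 to 7.7 log2 CPM in CSF3R_FIRST libraries, more than with either allele alone. Above were glycolysis genes (10 of 13), endoplasmic reticulum stress genes (8 of 10), cholesterol synthesis genes (9 of 15), transcription factors (5 of 14), dendritic cell genes (3 of 7), primary granule genes (7 of 11), genes described as lowered by RUNX1-ETO (4 of 9) and monocyte genes (4 of 19, with 2 below). Hspa5 was at 1.16, Pkm at 0.79 and the granule protease Ctsg at 1.19. Their adjusted p values ran from 2.68e-06 to 0.0297, and adjusted p = 0.109 to 0.386 with an estimated correlation. Adjusted over the list alone, those above were 12 glycolysis, 10 cholesterol synthesis, 5 monocyte genes and 8 transcription factors. In total 3004 genes departed from the sum, 1368 above and 1636 below, and 1176 by at least 2-fold. With library sizes alone the median of all genes was −0.20 rather than −0.04 on the log2 scale and the split was 1003 and 2725. The balance turned with DESeq2 size factors (1540 above, 1481 below), no filter (1396 and 1264), a filter of CPM over 1 (1592 and 1424), only the groups compared (1419 and 1357), DESeq2 (1664 and 1604), without EMPTY replicate 3 (1635 and 1539) and without CSF3R_FIRST replicate 3 (1330 and 1201).

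The genes changed at least 2-fold by each allele alone were then followed in both double groups. The 1080 genes raised by the receptor alone had a median of −0.58 on the log2 scale in RUNX1-ETO_FIRST against CSF3R_FIRST, with 523 lower and 32 higher with the fusion first (camera adjusted p = 5.52e-30, and adjusted p = 1.17e-08 with an estimated correlation). The 425 genes lowered by the receptor had a median of 0.36, with 98 higher and 29 lower (adjusted p = 1.93e-06, and adjusted p = 0.000106 with an estimated correlation). For the fusion alone, 1164 raised genes had a median of −0.22 (141 higher, 359 lower) and 882 lowered genes a median of −0.19 (44 higher, 170 lower), each at adjusted p = 0.000172, and adjusted p = 0.00306 and 0.000864 with an estimated correlation. The fusion sets also hold genes that the receptor alone changed. The 491 raised genes not past the test with the receptor had a median of 0.04 (95% interval over genes −0.04 to 0.10). The 401 such lowered genes had one of −0.14 (−0.19 to −0.10). A lower level with the fusion first was thus not shown for those 491 genes. When the sets were defined without the 2-fold minimum, the raised fusion set was no longer past the test (median −0.03, adjusted p = 0.111). The other medians then shrank to −0.08 for the lowered fusion set, −0.25 for the raised and 0.17 for the lowered receptor set, each still past the test. Under scaling by library sizes alone the fusion sets had medians of −0.11 (raised) and −0.12 (lowered). Against EMPTY, genes raised by the fusion had medians of 2.31 in RUNX1-ETO_FIRST and 2.56 in CSF3R_FIRST, and genes raised by the receptor medians of 1.97 and 2.68. Genes lowered by the fusion had medians of −1.34 and −1.16 and those lowered by the receptor of −0.92 and −1.17. These 8 medians share the EMPTY libraries with the definition of the sets. In 20 simulations both double groups were set equal to EMPTY, with noise drawn for each gene on its own. No absolute median passed 0.0888, so under that noise the shared controls alone gave values far smaller.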

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

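The tests on transcript length between the orders and on the mast cell list were chosen after those results were seen. The others were planned, but the 4 libraries weighed at the end of this section were picked from the data.

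Departures from the sum of the single alleles were picked out because the effect of one allele differed with the other present. That difference was tested on the log2 scale, where the sum is a product of folds. With the fusion first 2078 genes and 12 lists (6 with an estimated correlation) departed, with Bnip5 at 8.23, Angptl2 at 5.99, Tifab at 5.05, Spp1 at 4.59 and Retnlg at −7.18 on the log2 scale. With the receptor first 3004 genes and 12 lists (1 with an estimated correlation) departed, with Tifab at 4.39, Angptl2 at 4.32, Col5a3 at 4.21, Spp1 at 3.55 and Retnlg at −6.09. Genes with a group at or under the floor of 3 counts per library are left out here, and Retnlg in EMPTY lay only just above it.

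Among 50 divisions of the 12 libraries into groups of 3, the true one among them, 1 gave 2078 genes or more with the fusion first, the highest of the others being 1789, and 1 gave 3004 genes or more with the receptor first, the highest of the others being 57. In both orders 2 of the 50 gave 12 lists or more, the highest of the others being 12. Such divisions mix the effects of the alleles into the spread within groups, so they test for no difference among the groups rather than for additivity. They decide nothing about chance here.

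Each pair comparison allows 10 divisions of its 6 libraries, too few for a share under 0.05, and the true one was the 1 division with the result at its size. The other divisions put any difference between the groups into the spread within groups, which by itself lowers their counts. The values that follow therefore decide nothing about chance. For genes, the true values and the highest of the others were 2407 and 0 for the orders, 5117 and 0 for the fusion alone, 4347 and 0 for the receptor alone, 5768 and 0 for the fusion first, 7021 and 0 for the receptor first, 3454 and 1 for the receptor added second and 5895 and 0 for the fusion added second. For lists they were 12 and 8, 11 and 7, 9 and 8, 14 and 7, 12 and 9, 13 and 11, and 10 and 6, in that order. For the medians of the single-allele sets between the orders they were −0.22 and 0.13 for genes raised by the fusion, −0.19 and 0.11 for those lowered by it, −0.58 and 0.21 for those raised by the receptor and 0.36 and 0.14 for those lowered by it, the others in absolute size. Where deviations were correlated by replicate number (the fusion alone and the receptor first, against EMPTY), the other divisions that parted as many equal numbers gave 0 genes. That decides nothing either.

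Genes differed between the orders, and more fusion transcript in CSF3R_FIRST was weighed first. As the whole cause it would move genes lowered by the fusion, and not past the test with the receptor, further down in CSF3R_FIRST. Yet the median of these 401 genes was −0.14 (95% interval −0.19 to −0.10), lower in RUNX1-ETO_FIRST. The 491 genes raised by the fusion, and not past the test with the receptor, had a median of 0.04 (−0.04 to 0.10). The intervals in this paragraph are taken over genes, which are not independent replicates, and do not measure the spread between libraries. With library sizes alone the median of all genes between the orders was 0.10 rather than 0.00 on the log2 scale. The sets of this paragraph were not recomputed under that scaling, so the −0.14 argues only weakly against more fusion transcript as the whole cause. A trend with transcript length as the whole cause is argued against by 2279 of the 2407 genes that were still called after the correction. The values a stronger receptor program in CSF3R_FIRST needs were there: 358 genes raised by the receptor and not past the test with the fusion had a median of −0.63 (−0.75 to −0.57), and 119 genes lowered by it one of 0.45 (0.27 to 0.57). Other rows go against it for some lists. With the receptor alone 6 of 21 cell cycle genes rose and 1 fell (list test adjusted p = 0.132). Yet this list was lower in CSF3R_FIRST than in RUNX1-ETO_FIRST (adjusted p = 5.15e-10, or 0.00119 with an estimated correlation). Interferon response genes averaged 1.08 to 1.22 log2 CPM in CSF3R_ONLY libraries and 0.607 to 0.792 in EMPTY libraries, though the list was not past the list test there. They too were lower in CSF3R_FIRST than in RUNX1-ETO_FIRST (list test adjusted p = 0.0276, but adjusted p = 0.0539 with an estimated correlation). That call also ended with library sizes alone (0.0829) and without the 4 libraries low in long transcripts (0.123), so the interferon list weighs little here. A stronger receptor program stays a hypothesis. How far the orders also differ in the cells selected or the time in culture may add to it and was not tested.

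Mast cell, basophil and eosinophil genes were lower in RUNX1-ETO_FIRST than in CSF3R_FIRST. A smaller share of 1 cell population with a fixed profile, as the whole cause, would lower its specific members alike, but the 6 members with an EMPTY level under 1% of that in CSF3R_FIRST fell from −1.84 to −1.03 on the log2 scale, with a variance 3.88 times that given by their errors (Q per degree of freedom). Reads shared between paralogs, as the whole cause, are argued against by 9 of 12 members outside the protease and major basic protein families that fell. A change in both the share and the profile of such cells may still be present.

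Libraries EMPTY 3, RUNX1-ETO_ONLY 3, RUNX1-ETO_FIRST 1 and CSF3R_FIRST 3 deviated together within their groups. The mean of their 6 pairwise correlations across 8629 genes was 0.701, and the first axis of within-group deviations held 70.1% of their variance. These libraries were picked from the same deviations, so that correlation is not independent evidence that they belong together. Removing a trend with annotated transcript length left 0.654 and removing one with GC content left 0.716. This argues against a trend with either annotated value as the whole cause. Length effects that the annotation captures poorly are not covered. No biological explanation was tested, and RNA handling or library preparation shared by these 4 may remain.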

How the results depend on the processing

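The fits without the 4 libraries low in long transcripts and with a length correction were chosen after seeing the data; all other alternatives were planned, and all planned ones were run. Of 21253 values over 1167 combinations of a named gene and a comparison, 20217 kept their direction and their side of the threshold, 461 were no longer past it, 574 were newly past it and 1 reversed: Chac1 with the fusion alone against EMPTY was at 0.31 (adjusted p = 0.0446) without the 4 libraries; the cause was not tested. Counts fell when a 2-fold minimum was required, by construction, to 633 between the orders, 2046 with the fusion alone, 1505 with the receptor alone, 2341 and 2803 with both alleles (fusion first, receptor first), 1112 for the receptor added second, 2240 for the fusion added second, and 921 and 1176 for additivity. Without the 4 libraries 4449 genes differed between the orders and 3466 departed from additivity with the fusion first. The same counts were 4305 and 3480 with limma-voom and sample weights, and with only the groups compared the fusion alone gave 3388 genes; the cause was not tested. An estimated correlation lowered the lists past the threshold to 6 between the orders, 2 with the fusion alone, 6 and 6 with both alleles, and 6 and 1 for additivity, since it allows members to move together. Without the 2-fold minimum, the genes raised by the fusion had a median of −0.0298 between the orders (adjusted p = 0.111); the cause was not tested.

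With a replicate term, which pairs the libraries by number, counts were 2541, 5262, 4549, 5926, 7249, 3573, 6097, 2155 and 3223, in the same order. A length correction gave 2742, 5370, 4587, 6010, 7380, 3726, 6221, 2290 and 3225. Leaving out each library in turn gave 1718 to 2139 genes between the orders, 4244 to 5267 with the fusion alone, 3502 to 4494 with the receptor alone, 4998 to 6134 with the fusion first, 6415 to 7711 with the receptor first, 2757 to 3055 and 5107 to 5332 for the additions, and 1644 to 2338 and 2466 to 3174 for additivity. Lists past the threshold were then 9 to 13, 11, 9 to 10, 13 to 14, 10 to 13, 13, 10, 10 to 14 and 12 to 14. At this depth and with 3 libraries a group, changes near 1.5-fold are often missed: the simulated order comparison recovered 47% of them.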

Other observations

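Genes outside the comparisons above were read as levels. Hoxb8, the homeobox gene that the name of the line calls to mind, averaged 292 CPM in EMPTY (179 to 374 over its 3 libraries), 130.4 in RUNX1-ETO_ONLY (119.6 to 142), 456 in CSF3R_ONLY (428 to 492), 261 in RUNX1-ETO_FIRST (234 to 293) and 361 in CSF3R_FIRST (276 to 414). Esr1, the oestrogen receptor gene, averaged 64.9, 44.4, 155, 51.8 and 56.7 CPM in the same order, with 33.9 to 82.0 in EMPTY and 148 to 163 in CSF3R_ONLY. Both genes were chosen after their values were seen, and the labels do not describe how the line was made.

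Mitochondrial transcripts took 1.15% to 2.89% of the counts of a library, the highest share being that of EMPTY replicate 3. Replicates of a group varied more than counting error, with a chi-square per degree of freedom from 2.46 to 74.7 between pairs of libraries. Pairs without a library low in long transcripts lay between 2.46 and 6.20, and pairs with one at 15.2 or more. The highest values, 69.2 and 74.7, were those of EMPTY replicate 3 against the other EMPTY libraries.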
